A study of Mus musculus with 12 samples.

How the data were processed

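Total RNA from the hypothalamus of 12 mice was biotin-labelled and hybridised to Illumina bead arrays, per the labels. The labels place 3 mice in each of 4 groups (female control, female small litter, male control, male small litter) and number them as biological replicates. The deposited table of the authors gave, for each of 45281 probes and each array, the mean bead intensity, which was neither background-subtracted nor normalized between arrays, and a detection p-value, which per the values moved in steps of 1 in 936. The authors' processed values, also deposited, are on a log2 scale. The submitters' processing notes name lumi for them; its version and settings are not given in the sources used here. Set against the deposited intensities, these log2 values followed the log2 intensity of their own array with r of at least 0.99978. They had been brought to the same quantiles without background subtraction, with a median of 7.84 on every array. They cover 20791 probes, those with a detection p-value under 0.05 on at least 6 arrays. Their scale and normalization were found from the values, and they were used as an alternative.

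Probes were named through a table of genes supplied for the probes of the processed values. Of the 20791 probes, 18003 had 1 gene symbol, 6 had several and 2782 were not in the table; 17983 were matched by gene identifier to the current gene table, and 0 symbols changed. Probes with several symbols or none stayed as unnamed features. Agrp, Lepr and Ddx3y had no probe named in that table and were not analysed here. No coordinates were used.

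Intensities were normalized with neqc in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table), which applies a normexp background correction with negative control parameters inferred from the detection p-values, an offset of 16, quantile normalization and a log2 scale. Probes with a detection p under 0.01 on at least 3 of the 12 arrays were kept (19704), and of several probes of a gene the one with the highest mean stood for it (4190 tested genes had several detected probes). This left 13547 features, 10912 named and 2635 unnamed. Other probes of a gene did not always move alike, as the closing section describes. A linear model with a mean per group was fitted over all 12 arrays with lmFit and eBayes (8 residual and 4.84 prior degrees of freedom), and 5 contrasts were tested 2-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Fold changes carry the model's standard error. A gene not detected on any array of the dimmer group has only a bound: "at least N-fold" sets the brighter mean against, per array, the higher of the probe's own value and the lowest value among detected probes. The bound is taken from the measured means and carries no standard error, so by itself it does not show that a gene changed. No bound was computed for the interaction.

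The tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. By that rule, the 12 named genes with the largest change in each direction were taken among those past the threshold whose groups did not overlap, or, where under 5 passed, the 5 with the smallest p in each direction. Up to 4 members of each list that passed and up to 2 of the others with the smallest p could be named, and Npy, Pomc, Cartpt and Mc4r in every litter comparison and 7 sex-linked genes were always named where measured. Ddx3x stands outside this rule and was named after its values were seen.

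Of the 34 lists, 32 with at least 5 tested members were tested with camera (limma) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. They covered feeding neuropeptides and receptors, neurosecretory genes, sex steroid genes, imprinted genes, DNA methylation genes, glucocorticoid response, immediate early, clock, inflammation, endoplasmic reticulum stress, lipid synthesis, glutamatergic, GABAergic and monoamine genes, cell type markers (astrocyte, oligodendrocyte and precursor, microglia, endothelial and mural, meninges, blood, choroid plexus, ependyma and tanycyte, pituitary), markers of thalamus, cortex and hippocampus, striatum and hypothalamic subregions, and respiratory chain, ribosomal and proteasome genes. The Y-linked genes (3 measured) and the X-linked genes that escape inactivation (4 measured) were too few for a list test and are given gene by gene. Some genes stand in several lists, such as Tac2 in the neurosecretory and sex steroid lists.

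Alternatives were the authors' values, no background correction, an offset of 50, median scaling, no detection filter or detection on all 12 arrays, every probe on its own, only the arrays of a sex in the fit, eBayes with trend and robust, array weights, the replicate number as a block, an estimated correlation or fry for lists, and leaving out each array in turn. A further 3 were added after seeing the data: leaving out both arrays with the highest meningeal markers, leaving out male small litter 2 and 3, and the median signal as a covariate. A slide block was not run, as no slide is given in the sources used here.

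The steps were tested on simulated data made from the mean and residual spread of each feature. Features were drawn independently of each other with normal noise, with 1 draw per comparison. In each draw, 67, 67 and 66 features were given a change of 0.5, 1 and 2 on the log2 scale. Among 13547 features, changes of 0.5, 1 and 2 on the log2 scale were recovered for 40.3%, 91.0% and 100% of the changed features in females, 43.3%, 89.6% and 98.5% in males, 79.1%, 97.0% and 100% in the averaged comparison, 13.4%, 71.6% and 98.5% in the interaction, and 53.7%, 98.5% and 100% between the sexes. A shift of 0.3 in a list gave a camera adjusted p of 7.56e-16, and 1 of 28 lists that shared no member with it was called. As the features were independent, this does not test the preset correlation, and with 1 draw each the recovered shares are imprecise. The planted large changes loosen the adjusted threshold for the smaller ones, and no outlying array was simulated. The shares therefore do not give the power of the real litter comparisons.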

Results

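RNA levels were measured in the hypothalamus of 12 FVB/NJ mice, an inbred laboratory strain, at postnatal day 180. Mice raised in small litters, a model of overnutrition in early postnatal life, were set against control mice in both sexes, with 3 mice in each of the 4 groups and 1 Illumina bead array per mouse. The median bead signal was 112 to 127 on the 6 female arrays and 103 to 108 on the 6 male arrays, so brightness did not overlap between the sexes. Within females it was 121 to 127 in control mice and 112 to 118 in small-litter mice, also without overlap. Between 39.7% and 41.9% of the 45281 probes were detected on each array. After filtering, 13547 features entered the tests, of which 10912 carried a gene name. The number of arrays limits the precision of every value given here.

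Before the comparisons, 2 features of the arrays were measured. Markers of meningeal fibroblasts, the cells of the brain's outer membranes, had a list score of 1.20 in female control 3 and 1.23 in male control 2, against 0.40 in male small litter 2 and -0.15 or lower on the other 9 arrays. On the first principal component, which held 27.0% of the variance, male small litter 2 and 3 lay at 21.4 and 27.9, and the next highest array lay at 4.62. These 2 arrays also had the lowest median signals, 104 and 103. The 95th percentile of their signals was 1297 and 1244, against at least 1398 on every other array. The sex labels matched the sex-linked genes on all 12 arrays: Xist was detected on 6 of 6 female and 0 of 6 male arrays, and Kdm5d and Eif2s3y on 6 of 6 male and 0 of 6 female arrays.

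The first comparison asked how small-litter females differed from control females. Thalamus markers rose as a group in small-litter females, and groups of feeding neuropeptides, neurosecretory genes, sex steroid genes, hypothalamic subregion markers, meningeal, choroid plexus and red blood cell transcripts fell, by camera with a preset correlation. With an estimated correlation between genes, none of the 8 list calls in females held: the adjusted p was 0.451 for the thalamus, feeding, sex steroid, subregion, blood and choroid plexus lists, 0.521 for the neurosecretory list and 0.523 for the meningeal list. All 20 measured thalamus markers were higher, with a median log2 change of 0.22 (camera adjusted p = 6.07e-05). Among them were Cplx1 at 0.22 ± 0.11 (log2 change ± SE, n = 3 per group), Synpo2 at 0.31 ± 0.16, Grid2ip at 0.32 ± 0.17 and Tnnt1 at 0.35 ± 0.20. Of 22 feeding and energy balance neuropeptides, 17 were lower (median -0.14, adjusted p = 0.0166). Among them were Gal at -0.33 ± 0.21, Nts at -0.25 ± 0.13, Adcyap1 at -0.19 ± 0.12 and Pmch, the precursor of melanin-concentrating hormone, at -0.18 ± 0.10. Of 18 neurosecretory genes, 13 were lower (median -0.05, adjusted p = 0.0438). Crhbp, which binds corticotropin-releasing hormone, was at -0.45 ± 0.13, Scgn at -0.46 ± 0.16, Tac2 at -0.35 ± 0.16 and Sst, which encodes somatostatin, at -0.22 ± 0.15. Of 12 sex steroid receptor and dimorphic genes, 11 were lower (median -0.17, adjusted p = 0.00907), among them Ecel1 at -0.28 ± 0.19, Moxd1 at -0.29 ± 0.18 and the progesterone receptor gene Pgr at -0.18 ± 0.14. Of 16 markers of hypothalamic subregions, 11 were lower (median -0.13, adjusted p = 0.0166). Among them were Fezf1 at -0.35 ± 0.14, Lhx1 at -0.25 ± 0.14, Lhx8 at -0.57 ± 0.21 and Nkx2-1 at -0.32 ± 0.13. Lhx8 was not detected in any small-litter female and lay too close to the background for a bound.

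Meningeal, red blood cell and choroid plexus transcripts also fell as groups in small-litter females, by camera with a preset correlation. All 13 meningeal markers were lower in small-litter females (median -0.53, adjusted p = 0.00220), including Mgp at -0.77 ± 0.50, Slc22a6 at -0.71 ± 0.51, Serping1 at -0.56 ± 0.36 and Dcn at -0.40 ± 0.28. Slc22a6 was not detected in any small-litter female, so it was at least 1.38-fold lower. All 6 red blood cell transcripts were lower (median -0.26, adjusted p = 0.00529), with Hbb-b2 at -0.58 ± 0.19, Alas2 at -0.44 ± 0.27, Hbb-bt at -0.27 ± 0.19 and Hbb-bs at -0.26 ± 0.21. Of 10 choroid plexus markers, 8 were lower (median -0.24, adjusted p = 0.0166), with Ttr, the transthyretin gene, at -1.47 ± 0.76, Kl at -0.60 ± 0.26, Ecrg4 at -0.47 ± 0.22 and Col8a1 at -0.31 ± 0.13. The Ttr value was -0.61 without female control 2 and -0.92 without female small litter 1.

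Single arrays carried much of the change of the female lists. Without female control 3, the meningeal median was -0.05 (adjusted p = 0.937) and the choroid plexus median -0.09 (adjusted p = 0.107). The feeding peptides then had a median of -0.18 (adjusted p = 0.0538). Without female small litter 1, the thalamus median was 0.11 (adjusted p = 0.0618), the feeding peptide median -0.07 (0.425), the neurosecretory median 0.01 (0.469), the sex steroid median -0.11 (0.306), the choroid plexus median -0.20 (0.306) and the subregion median -0.10 (0.158). Without female control 1, the adjusted p was 0.0608 for the feeding peptides, 0.0608 for the subregion markers, 0.0663 for the neurosecretory list and 0.0676 for the blood transcripts. The blood median was -0.13 (adjusted p = 0.204) without female small litter 3. The neurosecretory list had an adjusted p of 0.15 without female control 2, 0.132 without female small litter 2 and 0.0519 without male small litter 1. Over the removal of each array, the medians reached 0.33 for thalamus and -0.24 for feeding peptides and -0.26 for sex steroid genes without female small litter 3, and -0.88 for meninges, -0.40 for blood and -0.37 for choroid plexus without female control 2. The neurosecretory median reached -0.12 without female control 1. The smallest sex steroid median was -0.08, without female control 2, and the smallest subregion median -0.08, without female small litter 3.

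No single gene passed the threshold in females by limma. By p alone, 453 of 13547 features had an unadjusted p under 0.05, against 677 by chance. The smallest adjusted p was 0.9996. Without female control 1, 1 gene passed, Gm5820, at 0.85 (adjusted p = 0.0240), against 0.62 ± 0.15 over all arrays. The named genes with the smallest p that were higher in small-litter females were Zbtb22 at 0.48 ± 0.09, Intu at 0.48 ± 0.10, Lpxn at 0.43 ± 0.10, Pik3cd, a catalytic subunit of phosphoinositide 3-kinase, at 0.59 ± 0.14 and Gm5820. The named genes that were lower were Lbp, which encodes lipopolysaccharide binding protein, at -0.76 ± 0.17, Vta1 at -0.44 ± 0.11, Plat, the tissue plasminogen activator gene, at -0.35 ± 0.09, Cetn4 at -0.43 ± 0.12 and Ndnf at -0.50 ± 0.14. Lbp was at least 1.43-fold and Ndnf at least 1.04-fold lower, since neither was detected in any small-litter female. Of the central feeding genes, Npy was at -0.21 ± 0.35, Pomc at -0.35 ± 0.27, Cartpt at -0.02 ± 0.19 and the melanocortin receptor gene Mc4r at -0.24 ± 0.23. The Cartpt value was 0.18 without female control 3 and 0.06 without female small litter 2, Npy was at -0.03 without female control 2, and Pomc was at -0.14 and Mc4r at -0.00 without female small litter 1. No list member passed when adjusted over the list alone.

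The next comparison set small-litter males against control males. Cholesterol and fatty acid synthesis genes and respiratory chain genes rose as groups in small-litter males, and glucocorticoid response genes fell, by camera with a preset correlation. None of the 3 calls held with an estimated correlation: the adjusted p was 0.728 for the lipid list, 0.648 for the respiratory chain and 0.648 for the glucocorticoid list. Of 17 cholesterol and fatty acid genes, 15 were higher (median 0.20, adjusted p = 0.000995), and 2 passed adjusted over the list alone (none over all genes): Dhcr7, the last enzyme of one branch of cholesterol synthesis, at 0.53 ± 0.15 (n = 3 per group) and Fdps, farnesyl diphosphate synthase, at 0.32 ± 0.09, both with an adjusted p of 0.0267. Idi1 was at 0.51 ± 0.18 and Lss at 0.34 ± 0.15. Of 74 respiratory chain genes, 54 were higher, by a small median of 0.07 (adjusted p = 0.00766). Among them were Atp5md at 0.76 ± 0.23, Ndufs5-ps, listed by name as a pseudogene, at 0.34 ± 0.12, Cox7a2 at 0.29 ± 0.10 and Ndufa12 at 0.25 ± 0.09. Of 20 glucocorticoid response genes, 17 were lower (median -0.33, adjusted p = 0.00174), with 1 past the threshold adjusted over the list alone, Map3k6 at -0.66 ± 0.16 (adjusted p = 0.0227), and Sgk1 at -0.66 ± 0.26, Klf9 at -0.47 ± 0.16 and Ddit4 at -0.33 ± 0.13. Map3k6 was at least 1.16-fold lower, since no small-litter male had it detected. Without male control 3, the glucocorticoid median was -0.13, the lipid median 0.11 and the respiratory chain median 0.06, each with an adjusted p of 0.0748. The respiratory chain median was 0.05 (adjusted p = 0.0816) without male small litter 3.

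**Figure D1:**
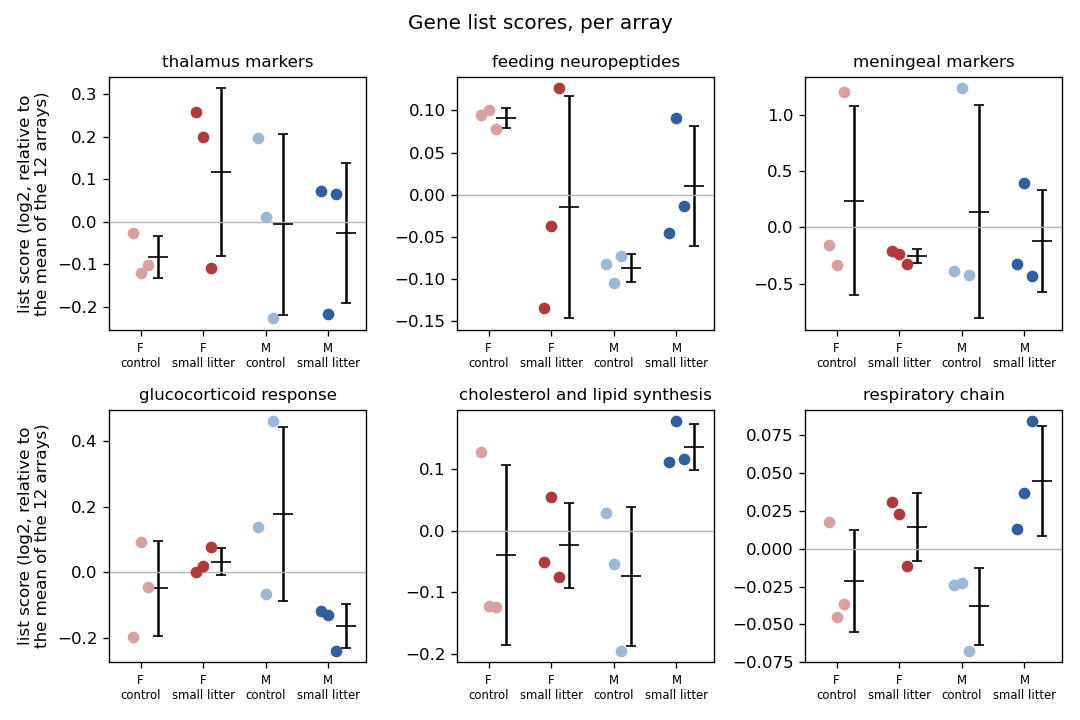
List scores (vertical axis, log2, the mean over a list's genes after each gene was centred on its mean over the 12 arrays) for 6 gene lists, by group, for females (F) and males (M). Each point is 1 array, and the bar beside each group is the mean ± SD of its 3 arrays. The glucocorticoid score of male control 3 was 0.46 and the meningeal scores of female control 3 and male control 2 were 1.20 and 1.23.

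No single gene passed in males by limma, and 1816 features had an unadjusted p under 0.05, against 677 by chance. Of the 10 splits of the 6 males, 2 gave as many, the real one included (highest other 1840). The smallest adjusted p was 0.227. The named genes with the smallest p that were higher were Tcirg1, a subunit of the vacuolar proton pump, at 0.72 ± 0.12, Mark4, a microtubule affinity-regulating kinase, at 0.84 ± 0.17, Hpgds at 0.61 ± 0.12, Zhx2 at 0.69 ± 0.14 and Sh3bp1 at 0.88 ± 0.18. The named genes that were lower were Man2b1, lysosomal alpha-mannosidase, at -0.71 ± 0.15, Kcnq3, a subunit of the M-type potassium channel, at -0.66 ± 0.12, Tap2 at -0.56 ± 0.11, Hivep3 at -0.49 ± 0.10 and Stt3a at -0.47 ± 0.09. Sh3bp1 was at least 1.32-fold higher and Kcnq3 at least 1.41-fold lower, as neither was detected on the dim side. Without male small litter 1, 661 genes passed (289 higher and 372 lower), among them these 10; without male control 2, and without male control 3, 1 passed. Npy was at -0.68 ± 0.35, Pomc at 0.31 ± 0.27, Cartpt at 0.15 ± 0.19 and Mc4r at 0.00 ± 0.23, none past the threshold. Without male control 3, Npy was at -0.12, Pomc at -0.02 and Cartpt at -0.05. Across the lists, 8 members passed adjusted over the list alone and none over all genes: besides the 3 above these were the synaptic genes Dlg4 at 0.46 and Gria4 at 0.50, the serotonin synthesis gene Tph2 at -0.53, and Dynlrb2 at 0.45 and Nes at 0.42 from the ependymal and tanycyte list. Tph2 was not detected in any small-litter male and was at least 1.30-fold lower.

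Averaged over the sexes, the small-litter comparison gives the mean of the female and male effects, which does not test whether both sexes moved. Respiratory chain genes and cholesterol and fatty acid synthesis genes rose as groups, and meningeal and choroid plexus markers fell, by camera with a preset correlation. None of these 4 calls held with an estimated correlation. Of 74 respiratory chain genes, 58 were higher (median 0.05, adjusted p = 0.000383; 0.429 with an estimated correlation), with Atp5md at 0.39 ± 0.16 (n = 6 per group), Ndufa12 at 0.17 ± 0.07, Ndufs6 at 0.16 ± 0.06 and Sdhd at -0.24 ± 0.10. Of 17 cholesterol and fatty acid genes, 15 were higher (median 0.14, adjusted p = 0.00117; 0.791 with an estimated correlation), with Idi1 at 0.30 ± 0.13, Dhcr7 at 0.20 ± 0.10, Fdps at 0.17 ± 0.06 and Sqle at 0.15 ± 0.09. The lipid median was 0.02 in females (adjusted p = 0.755) and 0.20 in males. The respiratory chain and lipid calls held on the removal of each of the 12 arrays, and the lipid median was 0.09 without male control 3. All 13 meningeal markers were lower (median -0.45, adjusted p = 0.0129; 0.930 with an estimated correlation), with Slc6a13 at -0.62 ± 0.40, Mgp at -0.56 ± 0.35, Ptgds at -0.52 ± 0.32 and Serping1 at -0.35 ± 0.25. Of 10 choroid plexus markers, 9 were lower (median -0.12, adjusted p = 0.0440; 0.791 with an estimated correlation), and Kl at -0.57 ± 0.18 and Col8a1 at -0.29 ± 0.09 passed adjusted over the list alone (adjusted p = 0.0414 for both) but not over all genes. Ace was at -0.22 ± 0.10 and Sostdc1 at 0.17 ± 0.12. The meningeal median was -0.13 (adjusted p = 0.478) without female control 3, -0.14 (0.746) without male control 2, -0.33 (0.307) without male small litter 1 and -0.32 (0.0688) without male small litter 3; with both female control 3 and male control 2 left out it turned, to 0.14 (adjusted p = 0.0493). The choroid plexus call was lost without female control 3 (adjusted p = 0.0896), female small litter 1 (0.157), male control 2 (0.152), male small litter 1 (0.307) or male small litter 3 (0.0829), and its median was -0.22 without male control 3.

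No single gene passed in the averaged comparison by limma, with 824 features at an unadjusted p under 0.05 (as many in 31 of 100 splits) and a smallest adjusted p of 0.814; 1 gene passed without male control 3. The named genes with the smallest p were Kcnh6 at 0.49 ± 0.10, Tcirg1 at 0.40 ± 0.09, H3c1 at 0.34 ± 0.08, Pik3ap1 at 0.32 ± 0.07 and Apba1 at 0.29 ± 0.07 on the higher side. On the lower side they were Thsd4 at -0.59 ± 0.14, Dnase2a at -0.50 ± 0.12, Kctd12b at -0.49 ± 0.11, Kcnq3 at -0.41 ± 0.09 and Stt3a at -0.31 ± 0.07. Kcnh6 and H3c1 were at least 1.11-fold and 1.01-fold higher, since no control array detected them. Npy was at -0.45 ± 0.25, Pomc at -0.02 ± 0.19, Cartpt at 0.06 ± 0.13 and Mc4r at -0.12 ± 0.16. Without male control 3, Npy was at -0.17. The Pomc value lay between -0.18 and 0.08 over the removal of each array, and that of Cartpt was -0.04 without male control 3.

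Whether the effect of the small litter differed between females and males was tested as an interaction, the effect in females minus that in males. Glucocorticoid response genes and thalamus markers had the higher effect in females, and feeding neuropeptides, lipid synthesis genes and endoplasmic reticulum stress genes had the lower one, by camera with a preset correlation. With an estimated correlation none of the 5 calls held, each with an adjusted p of 0.743. For glucocorticoid genes, 19 of 20 were on that side (median 0.47, adjusted p = 0.000941), with Map3k6 at 0.79 ± 0.22 (SE, n = 3 per group), Mt2 at 0.69 ± 0.26, Ddit4 at 0.48 ± 0.19 and Gpd1 at 0.47 ± 0.19. Map3k6 was detected in male controls alone, so its value is set against the background in the other 3 groups. For thalamus markers it was 17 of 20 (median 0.23, adjusted p = 0.0417), with Grid2ip at 0.73 ± 0.24, Amotl1 at 0.48 ± 0.19, Pdp1 at 0.39 ± 0.23 and Cplx1 at 0.30 ± 0.15. Of the feeding peptides, 18 of 22 were lower (median -0.23, adjusted p = 0.0253), with Vgf at -0.75 ± 0.29, Penk at -0.54 ± 0.29, Ucn3 at -0.46 ± 0.24 and Tac1 at -0.31 ± 0.17. Of the lipid genes, 15 of 17 were lower (median -0.20, adjusted p = 0.0253), with Dhcr7 at -0.64 ± 0.21, Lss at -0.58 ± 0.22, Idi1 at -0.41 ± 0.25 and Fdps at -0.30 ± 0.13. Of the stress genes, 15 of 21 were lower (median -0.17, adjusted p = 0.0497), with Calr at -0.76 ± 0.33, Creld2 at -0.59 ± 0.29, Hspa5 at -0.55 ± 0.33 and Pdia6 at -0.43 ± 0.24.

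The glucocorticoid call of the interaction held on the removal of each array, with a median of 0.21 without male control 3. The feeding peptide call was lost without female small litter 1 (adjusted p = 0.190), male small litter 1 (0.0557) or male small litter 2 (0.0609). The lipid call was lost without female control 1 (0.175), female small litter 1 (0.125), male control 3 (0.115, median -0.12), male small litter 1 (0.0608) or male small litter 2 (0.0609). The thalamus call was lost without female control 2 (0.0564), female small litter 1 (0.321), female small litter 2 (0.0822), male control 1 (0.386, median 0.11), male small litter 1 (0.0608) or male small litter 2 (0.305), and its median was 0.37 without male control 3. The stress gene call was lost without female control 3 (0.440, median -0.06), female small litter 1 (0.321), female small litter 2 (0.0675), male control 2 (0.0747), male control 3 (0.101), male small litter 1 (0.0608) or male small litter 3 (0.186), and its median was -0.25 without female control 1. In settings chosen after the data were seen, leaving out female control 3 and male control 2 together gave -0.0064 for the stress genes (adjusted p = 0.575) and 0.22 for thalamus (0.0583). Leaving out male small litter 2 and 3, so that 1 male of that group was left, gave -0.13 for the stress genes (0.244), -0.19 for feeding peptides (0.132), -0.14 for lipid genes (0.132) and 0.12 for thalamus (0.244).

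No single gene passed in the interaction by limma, with 1321 features at an unadjusted p under 0.05 and a smallest adjusted p of 0.404. As many such features came from 9 of 100 splits of the mice (highest other 1540). Without male small litter 1, 190 passed (108 higher and 82 lower), and without male control 3, 1. The named genes with the smallest p were Frmpd1 at 0.98 ± 0.21, Mob1b at 0.94 ± 0.19, Slco2a1, a prostaglandin transporter, at 0.72 ± 0.16, Intu at 0.65 ± 0.14 and Zbtb22 at 0.65 ± 0.13 on the higher side. On the lower side they were Lbp at -1.08 ± 0.24, Adat1 at -0.92 ± 0.20, Tmem176a at -0.92 ± 0.20, Zfp329 at -0.83 ± 0.16 and Elfn1 at -0.81 ± 0.17. Mob1b, Zfp329 and Lbp were not detected in at least 1 of the 4 groups, so their values are not exact. Without male small litter 1, Zbtb22, Frmpd1, Slco2a1, Zfp329, Elfn1, Tmem176a and Lbp passed among these 10, with adjusted p between 0.0362 and 0.0471. Npy was at 0.47 ± 0.50, Pomc at -0.65 ± 0.39, Cartpt at -0.16 ± 0.27 and Mc4r at -0.24 ± 0.32; Npy was at -0.09 and Pomc at -0.33 without male control 3, and Cartpt was at 0.04 without male control 3 and at 0.04 without female control 3. Of the members of the tested lists, 4 passed adjusted over the list alone and none over all genes. They were Tph2 at 0.67 from the monoamine list and 3 genes of the ependymal and tanycyte list, among them Dynlrb2 at -0.54 and Nes at -0.63. Tph2 was not detected in any small-litter male, so its value is not exact.

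Across the 13547 features, which are not independent replicates, the small-litter effect in females had a Pearson r of -0.122 and a Spearman rho of -0.142 with that in males, and 18 of 100 splits of the mice gave an r as far from 0. The r was -0.17 without female control 2 and -0.01 without female control 1. Features with an unadjusted limma p under 0.05 in both sexes numbered 84, and 27 of these had the same sign. Independent p-values would give 60.7. The p-values of both sexes share 1 residual spread per feature and are not independent, so the gap shows no excess over chance.

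**Figure D2:**
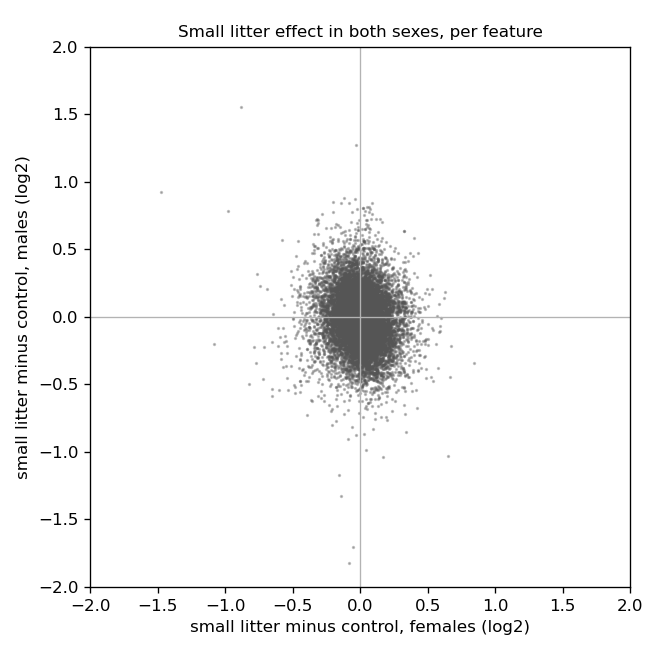
Small-litter effect per feature in females (horizontal axis, log2, small litter minus control) against that in males (vertical axis, same unit). Each point is 1 of 13545 features, and 2 features beyond a change of 2 on the log2 scale lie outside the frame; the cloud has a Pearson r of -0.122 over all 13547 features.

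The last comparison set males against females, averaged over the litter groups (n = 6 per sex). Genes of the sex chromosomes differed in the direction of their chromosomes: Xist, which silences one X chromosome in females, was at least 25.9-fold lower in males (adjusted p = 9.10e-12), and the Y-linked genes Kdm5d and Eif2s3y were at least 3.18-fold and 1.82-fold higher (adjusted p = 1.34e-08 and 4.17e-08). Uty, also Y-linked, rose by 1.07 ± 0.11 (log2, SE; adjusted p = 0.000563), a value that is not exact, since it was detected in 1 of 6 females. The X-linked genes that escape inactivation were lower in males, Kdm6a by -0.54 ± 0.07 (adjusted p = 0.00635), Ddx3x by -0.57 ± 0.09 (0.0124) and Eif2s3x by -0.41 ± 0.09 (0.0338). Kiss1, which encodes the reproductive neuropeptide kisspeptin, was lower in males by -1.11 ± 0.12 (2.16-fold, adjusted p = 0.00123), and all 6 females lay above all 6 males. Tfb1m, a mitochondrial rRNA methyltransferase, was lower by -1.53 ± 0.20 (adjusted p = 0.00377). It was detected in 1 of 3 male controls, so this value is not exact either. Its mean log2 intensity was 7.04 in female and 4.86 in male controls, and 7.01 in female and 6.13 in male small-litter mice (interaction -1.31 ± 0.39, adjusted p = 0.413).

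**Figure D3:**
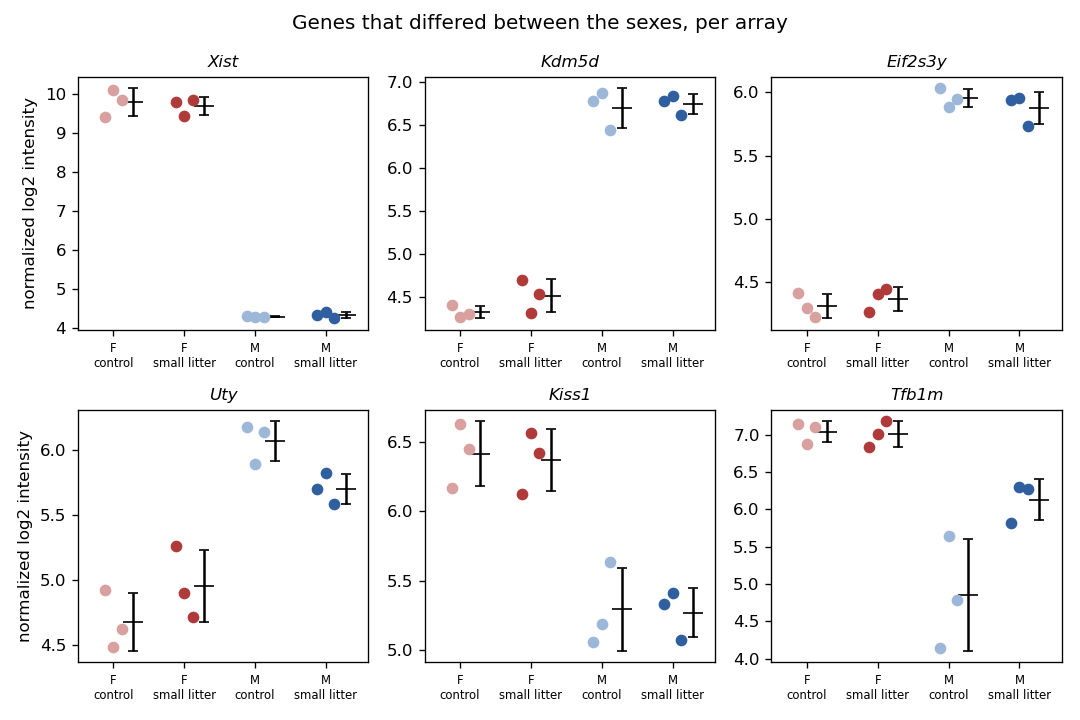
Normalized log2 intensity (vertical axis) of 6 genes that differed between the sexes, by group, for females (F) and males (M). Each point is 1 array, and the bar beside each group is the mean ± SD of its 3 arrays; the change between the sexes was 1.07 for Uty, -1.11 for Kiss1 and -1.53 for Tfb1m.

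In all, 631 features passed by limma, 325 higher and 306 lower in males, of which 232 and 235 carried a name; 8 differed by over 2-fold and 578 by under 1.5-fold. Besides the sex-linked genes, the named genes with the largest increases among those whose sexes did not overlap were Abca8b at 0.92 ± 0.14, Neurl2 at 0.78 ± 0.09, Klhl40 (at least 1.11-fold), Fam71e1 at 0.68 ± 0.12, Dnm1, the neuronal dynamin, at 0.66 ± 0.13, 1810044D09Rik (at least 1.22-fold), Kcnd1 at 0.65 ± 0.10, Islr2 at 0.64 ± 0.11 and Arhgap27 at 0.61 ± 0.12. Besides Kiss1 and Tfb1m, those with the largest decreases were Hbb-b2 at -0.78 ± 0.14, Pramel4 at -0.76 ± 0.12, Padi2 at -0.75 ± 0.19, Med1 at -0.67 ± 0.08, Tmem250-ps at -0.66 ± 0.12, Zdhhc5 at -0.64 ± 0.11, Chpf at -0.64 ± 0.09, Gm7609 at -0.62 ± 0.13 and Alpk2 (at least 1.09-fold). Each of these had all 6 males on one side of all 6 females. Neurl2, Fam71e1 and Kcnd1 were detected in 2, 1 and 1 of the 6 females, so their values are not exact. A second probe detected on all 12 arrays was compared for 6 of the named genes: it was at -0.10 for Padi2, -0.13 for Med1, -0.17 for Ndufb10 and 0.07 for Tef, none at a limma p under 0.05, and at 0.59 for Dnm1 and -0.38 for Gpr34. Among list members, the peptide-amidating enzyme gene Pam was lower by 0.54 on the log2 scale, the GABA receptor subunit gene Gabrb2 by 0.58, Ndufb10 by 0.50, H2-K1 by 0.58, Tef by 0.47, Gpr34 by 0.44, Nts by 0.38, Grin2b by 0.33, C1qa by 0.32 and the pituitary glycoprotein hormone gene Cga by 0.88. Tshb, not detected in any female, was at least 1.21-fold higher, and Sytl4 was higher by 0.55, Lamp5 by 0.46 and Dlg4 by 0.35 on the log2 scale. The mean log2 intensity of Dlg4 was close in female and male controls, at 8.60 and 8.65. In small-litter mice it was 8.47 in females and 9.11 in males (interaction -0.59 ± 0.17, limma adjusted p = 0.406). A probe with no gene name in the table used here, ILMN_2899599, was 8.10-fold higher in males, with all 6 males above all 6 females; it was singled out after its values were seen.

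Of 40 named sex genes, 23 passed on the removal of each of the 12 arrays, among them Xist, Kdm5d, Eif2s3y, Uty, Kdm6a, Kiss1, Tfb1m, Med1, Pam, Ndufb10, Gabrb2, Hbb-b2, Abca8b and Neurl2. The other 17 were lost in at least 1 removal, with adjusted p no higher than 0.105. Sytl4 was lost without male small litter 2 (adjusted p = 0.0549), Dnm1 without female control 3, female small litter 2 or male small litter 2 (up to 0.0561), and Arhgap27 without female small litter 2, male control 3 or male small litter 2 (up to 0.0554). Lamp5 was lost without female control 2, female small litter 2, male control 3 or male small litter 2 (up to 0.0554), and Gm7609 without female small litter 1, female small litter 2, male control 2, male small litter 2 or male small litter 3 (up to 0.0645). C1qa, Grin2b, Padi2 and Tef each passed only over all 12 arrays or without male small litter 1, with adjusted p up to 0.0952, 0.0832, 0.0940 and 0.1002 otherwise. Eif2s3x, 1810044D09Rik, Gpr34, H2-K1, Nts, Tshb, Cga and Dlg4 were lost in 8 to 10 of the removals. The total of 631 was 1454 without male small litter 1, and 145, 195, 347, 162, 235, 241, 205, 160 and 246 without female control 3, female control 2, female small litter 1, 2 and 3, male control 2 and 3, and male small litter 2 and 3. It was 85 without female control 3 and male control 2 together, 21 without male small litter 2 and 3 together, which leaves 1 male of that group, and 4 with the median signal of each array as a covariate, where the 631 changes kept a median of 89.4% of their size and their SE grew by a median of 3.36 times.

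No gene list passed between the sexes; the smallest camera adjusted p was 0.473, for microglia markers and for red blood cell transcripts, and with an estimated correlation it was 0.998. Adjusted over the list alone, 27 memberships passed, with genes such as Kiss1 counted in each of their lists; among them were B2m at -0.36, Hbb-bt at -0.41 and Col23a1 at -0.40, which did not pass over all genes.

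The other lists passed in no comparison, and each is given here in 1 sex only. Among all lists that did not pass in a comparison, the smallest camera adjusted p was 0.0538 in females and 0.145 in males. It was 0.0554 averaged over the sexes and 0.0979 in the interaction. In females, the medians were -0.05 for feeding receptors (adjusted p = 0.275), -0.07 for imprinted genes (0.0640), -0.01 for DNA methylation genes (0.625), -0.15 for immediate early genes (0.0538), -0.03 for clock genes (0.369) and -0.08 for inflammation genes (0.398). In males, the medians were 0.01 for glutamatergic synapse genes (adjusted p = 0.233), 0.01 for GABAergic synapse genes (0.919), 0.02 for monoamine genes (0.990), 0.01 for astrocyte markers (0.919), -0.03 for oligodendrocyte markers (0.933), 0.01 for oligodendrocyte precursor markers (0.726), 0.08 for microglia markers (0.750) and -0.13 for endothelial and mural markers (0.726). The remaining male medians were 0.06 for ependymal and tanycyte markers (0.726), 0.06 for pituitary genes (0.919), 0.03 for cortex and hippocampus markers (0.919), -0.00 for striatum markers (0.726), 0.03 for ribosomal proteins (0.233) and -0.01 for proteasome subunits (0.726). In males the median and the mean differed in sign for the oligodendrocyte (mean 0.04), proteasome (0.03), monoamine (-0.02) and pituitary (-0.04) lists, and the test followed the mean except for the pituitary list.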

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

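The counts over other splits of the mice were planned; the tests of second probes, of the tissue pieces, of male control 3 and of male small litter 2 and 3 were chosen only after the results were seen. The effect of the small litter differed between females and males, by the interaction, for 5 gene lists. The median interaction was -0.23 for feeding neuropeptides (camera adjusted p = 0.0253), 0.47 for glucocorticoid response genes (0.000941), -0.17 for endoplasmic reticulum stress genes (0.0497), -0.20 for lipid synthesis genes (0.0253) and 0.23 for thalamus markers (0.0417), each with an adjusted p of 0.743 with an estimated correlation. With other splits of the mice, 45 of 100 splits gave as many as these 5 lists (highest other 13), so chance cannot be excluded for their number.

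For the other counts of lists, 52 of 100 splits gave as many as the 4 of the averaged comparison (highest other 13), so chance cannot be excluded there. A count of 0 is met by every split whatever the data, so the 100 of 100 splits that met the 0 lists between the sexes (highest other 15) say nothing about chance. As many lists as the 8 in females came from 3 of 10 splits (highest other 15). As many as the 3 in males came from 8 of 10 (highest other 7, median other 4). Chance cannot be excluded for either count, and 10 splits are too few for a share under 0.05. For genes, the same holds of the count of 0, which was met by 10 of 10 splits in females and 10 of 10 in males (highest other 0 in both, too few splits for a share under 0.05), by 100 of 100 splits in the averaged comparison (highest other 1) and by 100 of 100 in the interaction (highest other 2). Between the sexes, 1 of 100 splits, the real one, gave as many as 631 genes (highest other 48), so such a count was rare among splits. By an unadjusted limma p under 0.05 the real split gave 3283 features, against 2642 in the highest other. The other splits mix the sexes, which widens their residual spread and lowers their counts.

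The sex differences outside the sex-linked genes were weighed against a difference between female and male arrays that acts on single probes, since median brightness did not overlap between the sexes. All 10 detected probes of 6 sex-linked genes (Xist, Kdm5d, Eif2s3y, Uty, Kdm6a, Eif2s3x) passed in the direction of the sex chromosomes. Xist had 4 of these probes and Kdm6a had 2 (at -0.54 and -0.55), which argues against such a probe-level difference for these genes. The other genes had 1 probe each, the one already called, so no further probe tests them. Ddx3x, with 2 detected probes, was left out of this set and of the next. For 156 other called genes with another probe detected on all 12 arrays, that probe moved by a median of 29.1% of the called change (95% interval 17.1% to 39.6%), in the called direction for 103, and with an unadjusted p under 0.05 it moved with the call for 50 genes and against it for 11. Called probes are picked for their size. For 97 genes picked in control mice and measured in small-litter mice the share was 29.1% with an interval of -9.34% to 58.4%. Over 3337 genes not picked by size, a probe's sex change in controls correlated with that in small-litter mice at a mean r of 0.382. With the other probe's it was 0.0973, at 24.9% of the same-probe covariance. That share was 23.2% for male small litter 2 and 3, and -2.16% for female control 3 and male control 2. Probes of 1 gene correlated weakly in all 5 comparisons (r 0.236 to 0.264 across these genes, which are not independent replicates). In females the litter effect varied less than its noise (variance 0.0127 against 0.0162), so a weak r is no reference there. A low share was also met within 1 sex. A probe-level difference and a biological sex difference cannot be told apart for these genes. Brightness and sex are confounded (r = -0.892 over the 12 arrays), so the 4 genes left with brightness as a covariate say little: the 631 changes kept a median of 89.4% of their size, 43 turned, and their SE grew by a median of 3.36 times, which leaves brightness open.

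The higher thalamus markers and lower hypothalamic lists in small-litter females were weighed against tissue pieces that differed in how much thalamus they held. Over the 12 arrays, as deviations from group means, a score of 19 thalamus markers and a score of 51 hypothalamic genes had Pearson r = -0.849 (permutation p = 0.0255) and Spearman rho = -0.713 (permutation p = 0.0517), and r = -0.688 without the 2 arrays farthest on the thalamus score. Within females r was -0.909 and within males -0.822. This relation within groups is what unequal pieces would give, and a candidate explanation of the group difference is that more thalamus was taken with the hypothalamus of female small litter 1 and 2, at thalamus scores of 0.27 and 0.20; female small litter 3 was at -0.10, level with female controls, and male control 1 was as high, at 0.21. An effect of the litter on these genes was not tested apart from it and stays open.

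The lists that passed in males were weighed against single mice. Without male control 3, the glucocorticoid median was -0.13 (adjusted p = 0.0748), so the change may come in large part from a high glucocorticoid response in that 1 control mouse. Leaving out male small litter 2 and 3, which stood apart, left 1 small-litter male against 3 controls, with the spread taken from the other groups: the lipid median was then 0.138 (adjusted p = 0.00863) and the respiratory chain median 0.0383 (adjusted p = 0.189). A single mouse excludes nothing, so whether those arrays account for either list stays open. Without male control 3 both of these lists had an adjusted p of 0.0748, and an effect of the litter on them remains an open hypothesis.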

How the results depend on the processing

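The settings that left out 2 arrays together or added brightness were chosen after seeing the data. The gene counts of 0 in the 4 litter comparisons held under every alternative except single removals, which gave 0 to 1 in females, 0 to 661 in males, 0 to 1 averaged and 0 to 190 in the interaction. Of 2436 results for named genes and lists under the other alternatives, 2262 kept direction and side of the threshold, and of 2325 with single arrays removed, 2103 did. No gene passed in the 4 litter comparisons under the other alternatives. For genes there only the direction could change, so the share says little about how firm they are. The sex count of 631 was 1071 with the authors' values, 1076 without background correction, 984 with an offset of 50, 964 with every probe tested, 1144 with trend and robust, 1686 with array weights, 85 without both meningeal arrays, 21 without male small litter 2 and 3, 4 with brightness, and 145 to 1454 over single removals; the cause was not tested. Of the 631 calls, 531 recurred with the authors' values, 627 with weights, 141 without female control 3, 79 without both meningeal arrays, 20 without male small litter 2 and 3 (1 male of that group left) and 4 with brightness, where 43 turned direction and the SE grew by a median of 3.36 times.

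With an estimated correlation, and with fry, 0 lists passed in every comparison. With the authors' values and the preset correlation each list call was kept, but with smaller medians. In females these were -0.08 for sex steroid genes, -0.06 for subregion markers, -0.03 for neurosecretory genes and -0.13 for choroid plexus. The glucocorticoid median was -0.20 in males and 0.27 in the interaction. Lists in females numbered 5 without both meningeal arrays, 5 with brightness and 2 to 12 over single removals. Without both meningeal arrays the meningeal (median -0.05, camera adjusted p = 0.828), feeding peptide (-0.18, 0.0639) and choroid plexus (-0.09, 0.0639) calls were lost. The averaged choroid plexus call was lost there too (-0.10, 0.199). With brightness, 6 of the 8 female calls were lost: thalamus (median 0.13, adjusted p = 0.124), feeding peptides (-0.13, 0.156), sex steroid genes (-0.18, 0.215), neurosecretory genes (-0.0075, 0.723), subregion markers (-0.13, 0.418) and choroid plexus (-0.25, 0.0974). The meningeal (0.00213) and blood (0.0425) calls were kept, and the rest of the 5 lists passing with brightness had not passed in the main test. Brightness did not overlap between the litter groups of females, so these losses cannot tell an effect of the litter from one of brightness. Averaged, they numbered 7 without male small litter 2 and 3, 8 with brightness and 2 to 8 over removals. In the interaction they numbered 3 without both meningeal arrays (stress and thalamus lost), 1 without male small litter 2 and 3 (glucocorticoid kept, the other 4 lost), 4 with brightness (lipid lost at -0.16, adjusted p = 0.0694, and thalamus at 0.13, 0.177) and 1 to 9 over removals. In males they numbered 0 to 4 over removals. Between the sexes, 1 passed without male small litter 2 and 3 and 1 with brightness. The correlation of the effects in both sexes was -0.173 to -0.0124 over removals.

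Directions turned as follows; the cause was not tested. Cartpt in females was at 0.0025 with median scaling, 0.19 without both meningeal arrays and -0.13 to 0.18 over removals. Mc4r in males was at -0.22 with weights, -0.0481 without both meningeal arrays, -0.14 with brightness and -0.22 to 0.22 over removals, and in the interaction it was at 0.0734 with weights. Averaged and without both meningeal arrays, Serping1 was at 0.0349, Slc6a13 at 0.0309 and the meningeal list at 0.14. With brightness, Pgr in females was at 0.13, Cartpt averaged at -0.0122, and between the sexes Padi2 at 0.0929, Nts at 0.0811, Dlg4 at -0.0020, Grin2b at 0.15 and C1qa at 0.0516. Hspa5 in the interaction was at 0.0060 without male small litter 2 and 3. Over removals, Cartpt reached -0.0526 to 0.30 in males, -0.0350 to 0.17 averaged and -0.32 to 0.0392 in the interaction, Pomc -0.0184 to 0.49 in males and -0.18 to 0.0816 averaged, and Npy -0.0868 to 0.76 in the interaction.

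Replicate numbers did not pair the mice: deviations of the 18 same-numbered pairs correlated at -0.126 to 0.111, with 1 pair over 0.1, and 1 of 12 arrays was closest to its own number. With the replicate block the sex count was 352, and the block changed the gene count of no other comparison. Dim probes limit what can be seen, since about 40% of the probes were above background on any array.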

Other observations

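Several genes were set apart in 1 or 2 mice; these were picked after their values were seen and are given as values. In male control 3, Plin4 was 6.73-fold, Sult1a1 4.28-fold, Cdkn1a 2.67-fold and Fkbp5 2.25-fold above the median of the other arrays, all glucocorticoid response genes, and the neuropeptide genes Npy and Avp were 3.25-fold and 2.79-fold above it. In the same mouse, Klk6 lay -1.86 and Gkn3 -2.01 from that median on the log2 scale, and Apoc1 was 2.39-fold above it. In female control 2, the activity-regulated gene Egr3 was 8.37-fold and Fosb 2.58-fold above the median. The prolactin gene Prl, a pituitary transcript, had a log2 intensity of 8.60 in female small litter 3 and 7.78 in female control 2. S100a8, a neutrophil transcript, was 6.85-fold above the median in female small litter 2. Meningeal genes were high in both male control 2 and female control 3, at log2 intensities of 8.40 and 8.15 for Ogn, 9.35 and 9.19 for Slc13a4 and 12.28 and 12.20 for Igf2.

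The 661 genes that passed in males when male small litter 1 was left out had a median change of 0.59 in the called direction in male small litter 2 and 3 and of 0.09 in male small litter 1, taken against the male controls. They were picked on male small litter 2 and 3 against these same controls, so the gap is larger than an independent measurement would give, and the shared controls alone would move male small litter 1 in the called direction. Among those with the largest changes were Tfb1m at 1.43, Cd200 at 1.23, Mapk8ip1 at -1.24, Shf at -1.19 and Irs2, an insulin receptor substrate, at -1.14. On the array of male small litter 1 these were at 0.96, 0.07, -0.01, -0.21 and -0.29 from the male controls.

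A pair of bright probes fell to the background on single male arrays. The Maged1 probe had a signal of 68.2 in male control 1 and at least 6333 on every other array, and the Pdia3 probe 69.0 and 70.4 in male control 1 and 2 and at least 1285 elsewhere. The change of Pdia3 between the sexes, -3.23 (limma adjusted p = 0.0466), includes these arrays, and Pdia3 is 1 of the 8 features past the threshold that differed by over 2-fold.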
